A study of Mus musculus with 4 samples.

How the data were processed

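Total RNA from the renal cortex of male mice of 4 groups (ND-WT, DM-WT, ND-KO and DM-KO) was labelled with biotin and hybridised to 1 CodeLink bioarray per group, per the labels. The arrays were scanned on an Axon GenePix scanner and read with CodeLink Expression Analysis software, per the labels. The deposited scanner tables give, per the file headers, each spot's mean intensity and the median intensity of its local background on a linear scale, neither subtracted nor scaled, with a quality mark for usable, empty or poor spots. The deposited series value table also holds intensity on a linear scale. Each of its columns equalled that array's spot mean minus background median, divided by 1 constant, for 100% of compared probes within 0.1%, with constants of 43.9, 38.1, 45.0 and 46.9 for ND-WT, DM-WT, ND-KO and DM-KO. Its column medians were 0.926, 0.930, 0.929 and 0.930. Genes were not centred in it. The rule by which the authors chose the constant stays unknown, because the design text ends before it describes the normalization.

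From the scanner tables, intensities were background-corrected with normexp at an offset of 50 over all spots in limma 3.58.1 under R 4.3.3, converted to log2 and quantile-normalized between the 4 arrays. The log2 values are thus computed from the deposited intensities. Control, blank and bacterial spots were left out after background correction, and spots marked poor were set to missing. Of 10752 spots, 10032 were gene probes, 300 negative controls and 180 bacterial controls. A probe was called measured on an array where its spot was marked usable, and otherwise had only a bound there. A bound set the bright array's value against the higher of the dim probe's own value and the lowest usable value of the dim array. Negative controls had a median background-subtracted intensity of 3.95, 3.70, 3.91 and 3.36, and 3, 3, 6 and 5 of them were marked usable. Between spots of 1 bacterial probe the median coefficient of variation was 7.50%, 9.06%, 7.69% and 7.72%.

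Probes were named through the platform's annotation and, where that was silent, through transcript accessions. In this way 9209 probes had 1 symbol (8923 from the platform and 286 from an accession), 1 had several and 822 had none. Probes of a gene were averaged, which affected 129 of 9077 genes. Older symbols were updated, and near-identical genes such as Hspa1a and Hspa1b may share signal on 1 probe.

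The groups, comparisons, gene lists, naming rule and alternatives were set before the data were examined, except where stated. The comparisons were DM-WT with ND-WT, DM-KO with ND-KO, DM-KO with DM-WT and ND-KO with ND-WT. Each was described by the count of genes differing by at least 2-fold among those measured on both arrays, with no p-value, because each group has 1 array. Diabetes and genotype were tested in 1 additive limma fit over the 4 arrays with 1 residual degree of freedom per gene, moderated across genes, for 6512 genes measured on at least 2 arrays, with values not above background entered as they were. Calls needed a Benjamini-Hochberg adjusted p under 0.05. The interaction was computed as a value only. A simulation of unchanged genotype effects drew 1000 sets.

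The gene lists covered glucose handling, fatty acid oxidation and ketogenesis, cholesterol and fatty acid synthesis, the respiratory chain and ATP synthase, and chemokines, cytokines and adhesion. They covered macrophage and monocyte, lymphocyte and neutrophil markers, complement, antigen presentation and interferon response, extracellular matrix and fibrosis, tubule injury, oxidative stress and NRF2 targets, and endoplasmic reticulum stress. Further lists were renin-angiotensin and blood pressure, clock genes, androgen-dependent male kidney genes, female-biased kidney genes, cell cycle, immediate early genes and heat shock. Cell type lists held proximal tubule, podocyte, thick limb and distal tubule, collecting duct, endothelial, smooth muscle and pericyte, red cell, adrenal, adipocyte and skeletal muscle markers. The last were the cholecystokinin and gut hormone system, housekeeping genes and the 30 annotated genes on each side of Icam1. A list's median log2 difference was placed among 10000 random lists of the same size matched on mean level in 10 classes, where at least 5 members were measured. A median outside the central 95% was called. This describes these arrays and is no test of the conditions.

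Genes were named by a fixed rule, under which probes without a symbol were counted but neither ranked nor named. Icam1 came first, then Cck, Cckar, Cckbr and Spp1, then the 10 highest and 10 lowest of each comparison and of the interaction, and at most 5 bounds per direction. Genes at least 2-fold different in both genotypes, the 10 lowest p-values per direction in limma and up to 4 members per list with the largest differences followed. Members passing limma adjusted over a list alone were named from that table.

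The limma step was tested on simulated data for diabetes over 6512 genes, in 20 sets with 200 changed genes each. It called 4.55% of genes changed 1.5-fold, 46.1% of those changed 2-fold and 72.2% of those changed 4-fold, and 0.244% of its calls were unchanged genes. The simulated noise was normal, with spreads drawn from those of the genes without the largest, and no array defect was planted. These shares, and those of the 2-fold rule, therefore do not cover a defect of 1 array. The 2-fold rule for DM-WT against ND-WT found 50.2% of genes changed 2-fold and 100% of those changed 4-fold. Planted lists of 25 genes in that comparison, over 6055 genes, were called in 4% of cases with no shift, 78% at a shift of 0.1 and 100% at 0.2. Their members were drawn at random, so these shares do not cover lists of genes that vary together or lists of other sizes.

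Alternatives were the series value table, median scaling between arrays, normexp with an offset of 16, no background correction, no filter on dim probes, genes measured on all 4 arrays only, the brightest probe per gene, random lists not matched on level, and limma with an intensity trend, robust moderation or no covariate. Leaving out columns 44 to 48 of the upper block on all arrays, before normalization, was added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.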

Results

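Gene expression was measured in the renal cortex of male C57BL/6J mice on 4 one-colour CodeLink bioarrays, on which biotin-labelled cRNA is read through a fluorescent streptavidin conjugate. Wild-type mice (WT) and mice lacking ICAM-1 (KO), an adhesion molecule through which leukocytes leave the blood and enter tissue, received either streptozotocin or citrate buffer at 8 weeks of age. Streptozotocin, a toxin of pancreatic beta cells, was given at 200 mg/kg, and kidneys were taken 12 weeks later. The groups were nondiabetic WT (ND-WT), diabetic WT (DM-WT), nondiabetic KO (ND-KO) and diabetic KO (DM-KO). The labels give 5 mice per group but only 1 array per group, and do not say whether that array held pooled RNA or the RNA of 1 mouse. There were therefore no replicates, and a difference between 2 arrays has no replicate check and is described by its size. The only tests were limma fits over all 4 arrays, in which each gene's spread is its departure from additivity of diabetes and genotype, so a p-value covers the spread between these arrays only.

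Of 10032 gene probes, 6496 (64.8%) gave a usable spot on ND-WT, 6301 (62.8%) on DM-WT, 6609 (65.9%) on ND-KO and 6641 (66.2%) on DM-KO. The median background-subtracted intensity was 43.5, 37.7, 44.3 and 46.3 on these arrays, beside a median local background of 47, 46, 46 and 46. Across genes, which are not independent replicates, array pairs correlated at 0.982 to 0.995, and the 3 lowest values all involved DM-WT. Bacterial control transcripts added to the RNA stood at 0.554 of their ND-WT level on DM-WT, against 1.25 on ND-KO and 1.21 on DM-KO. On DM-WT, 35 of the 38 bright probes that lay more than 2-fold below the other arrays were printed in columns 44 to 48 of the upper block. These 35 were 20.0% of the 175 bright probes there, against 0.0785% of 3822 elsewhere. Counts of genes are therefore also given with those edge spots left out on all arrays, an alternative chosen after seeing the data, and genes printed there are named as edge genes.

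**Figure D1:**
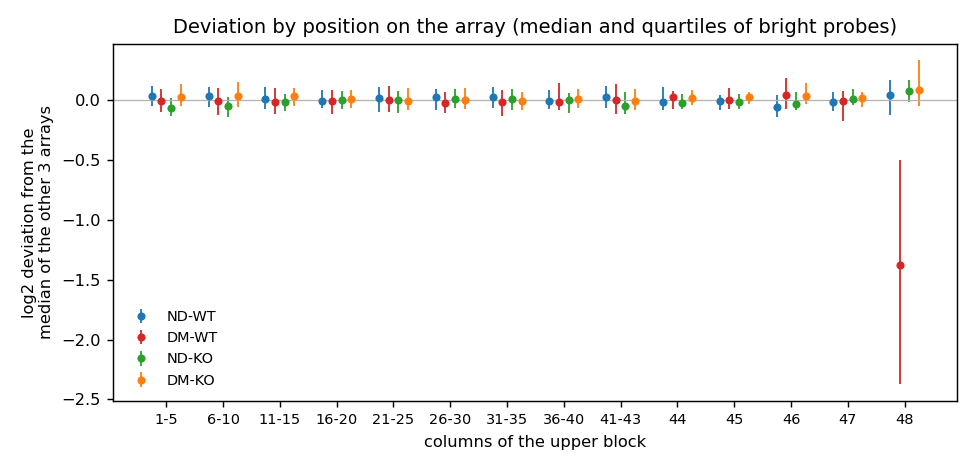
Log2 deviation of bright probes from the median of the other 3 arrays (y axis) by column of the upper block of spots (x axis) for the 4 arrays, with points at medians and bars over the quartiles. In column 48 the DM-WT median was -1.38, while the medians of the other 3 arrays lay between 0.04 and 0.08.

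Icam1 was not analysed here, so the genotype labels were not checked by the targeted transcript itself. Icam2, a related endothelial adhesion molecule, differed by -0.08 on the log2 scale between ND-KO and ND-WT and by 0.00 between DM-KO and DM-WT. Genes that neighbour Icam1 on its chromosome had a median log2 difference of -0.03 between ND-KO and ND-WT, at percentile 20.5 of matched random lists. Cck, which encodes the peptide hormone cholecystokinin, had log2 intensities of 7.12 on ND-WT, 9.06 on DM-WT, 7.57 on ND-KO and 8.02 on DM-KO. Cckar, which encodes a cholecystokinin receptor, was lower with diabetes in both genotypes, with log2 differences of -0.63 in WT and -0.30 in KO. Cckbr, which encodes the other receptor, was not above background on any array. The spot of Spp1, which encodes osteopontin, was of poor quality on DM-WT, and Spp1 stood 0.65 higher on DM-KO than on ND-KO on the log2 scale.

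The first comparison asked how diabetes altered the cortex of mice with intact ICAM-1. Cyp4a14, a fatty acid hydroxylase, was 11.2-fold higher on DM-WT than on ND-WT, and Aldh1a1, a retinaldehyde dehydrogenase, was 3.19-fold higher. Irf7, a regulator of the interferon response, was 5.58-fold higher, Lgals3bp was 4.04-fold higher and Ifit3 was 2.70-fold higher. Cck was 3.84-fold higher. Gdf15, a stress-induced cytokine, Sgk1, a kinase induced by corticosteroids, Ephx1, an epoxide hydrolase, and Rcan1, an inhibitor of calcineurin, were 2.66-fold, 2.65-fold, 2.62-fold and 2.54-fold higher. Genes measured only on DM-WT were higher by at least 15.3-fold for Ugt1a2, 4.28-fold for the cell cycle inhibitor Cdkn1a, 2.67-fold for Ubd, 2.54-fold for Ighm and 1.79-fold for Phlda3.

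Among the lower genes, Cyp4a12a, an androgen-dependent fatty acid hydroxylase, had a log2 difference of -1.56. Pzp stood at -1.09, Ces1g, a carboxylesterase, at -0.92 and Hpd, an enzyme of tyrosine breakdown, at -0.91. The other 6 of the 10 lowest genes with a symbol were edge genes, Slc25a3 at -4.75, Pnpla3 at -3.37, Tbca at -1.70, Acadsb at -1.62, Orc3 at -1.21 and Usp14 at -1.09. The 5 lowest bounds were also edge genes, Cox6a1, Lamp2, Atp5g1, Tram1 and Pigq. In all, 27 of 6055 genes measured on both arrays were at least 2-fold higher and 9 were at least 2-fold lower, and 7 of the 9 were edge genes, 1 of them an unnamed probe. With edge spots left out the counts were 26 and 2 of 5827. With edge spots kept, the balance turned to 31 and 34 with no filter on dim probes and to 17 and 22 under median scaling. Genes past a 2-fold bound numbered 4 higher and 21 lower, and 4 and 0 with edge spots left out. Genes past such a bound are counted when there is no filter, so most of the 34 lower genes there rest on edge spots.

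All 25 measured genes of antigen presentation and interferon response were higher on DM-WT than on ND-WT, 15 of them by at least 1.5-fold. Their median log2 difference was 0.70, at percentile 100 of matched random lists, with Irf7 at 2.48, Ifit3 at 1.43, Ifit1 at 1.34 and the edge gene Irgm1 at 1.20. All 13 measured tubule injury genes were higher, with a median of 0.45 (percentile 100), including Gdf15 at 1.41, the cytokine receptor Tnfrsf12a at 0.89 and S100a6 at 0.69. Macrophage and monocyte markers had a median of 0.28 (percentile 100), with the protease Ctss at 0.93, the complement component C1qa at 0.90 and lysozyme Lyz2 at 0.85. Immediate early genes stood at 0.30, with Ccn1 at 0.67 and Myc at 0.43. Cell cycle genes stood at 0.20, with Cdk1 at 0.38, and chemokines, cytokines and adhesion genes at 0.19, with Cxcl10 at 1.15. Smaller medians outside the central 95% of random lists were 0.12 for complement, 0.12 for thick limb and distal tubule markers, 0.12 for lymphocyte markers and 0.11 for extracellular matrix and fibrosis. Members of these included Serping1 at 0.64, the calcium-binding protein Calb1 at 0.93, the immunoglobulin J chain gene Jchain at 0.45 and the matrix protein Sparc at 0.60. The complement and macrophage lists share C1qa, C1qb and C1qc. Glucose handling genes had a median of 0.15 (percentile 99.8), yet G6pc stood at -0.86, and relative to all genes their median became -0.0233 under median scaling.

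Androgen-dependent male kidney genes were lower on DM-WT in 10 of 10 measured cases and by at least 1.5-fold in 7, with a median of -0.72 (percentile 0). They included the edge gene Cyp2e1 at -0.90, Acsm3 at -0.76, Cyp4b1 at -0.76 and ornithine decarboxylase Odc1 at -0.74. Proximal tubule transporters and markers had a median of -0.11 (percentile 0.02) and clock genes a median of -0.12 (percentile 0.21), with Slc22a18 at -0.55 and Rora at -0.65. Medians inside the central 95% were 0.01 for fatty acid oxidation and ketogenesis, -0.10 for cholesterol and fatty acid synthesis, 0.06 for the respiratory chain and ATP synthase and 0.07 for oxidative stress and NRF2 targets. Under median scaling the medians of the last 2 lay below the median of all genes, although among matched lists NRF2 targets moved to percentile 99.2, above the central 95%, and the respiratory chain to 91.2. Also inside were endoplasmic reticulum stress at 0.02, heat shock at 0.08, renin-angiotensin and blood pressure at 0.08, podocyte markers at 0.04 and collecting duct markers at 0.07. So were endothelial markers at 0.06, smooth muscle and pericyte markers at 0.09, red cell and haematopoietic markers at 0.10, adrenal markers at 0.05, housekeeping genes at 0.09 and neighbours of Icam1 at -0.03. Female-biased kidney genes had a median of -0.18 but a mean of 0.46, because Cyp4a14 belongs to that list. Under at least 1 alternative the calls for glucose handling, lymphocyte markers, complement, clock genes and thick limb markers ended, that for thick limb markers also with edge spots left out. Cholesterol synthesis (percentile 1.33 with edge spots left out), NRF2 targets, renin-angiotensin, female-biased, collecting duct and housekeeping genes passed outside the central 95%.

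**Figure D2:**
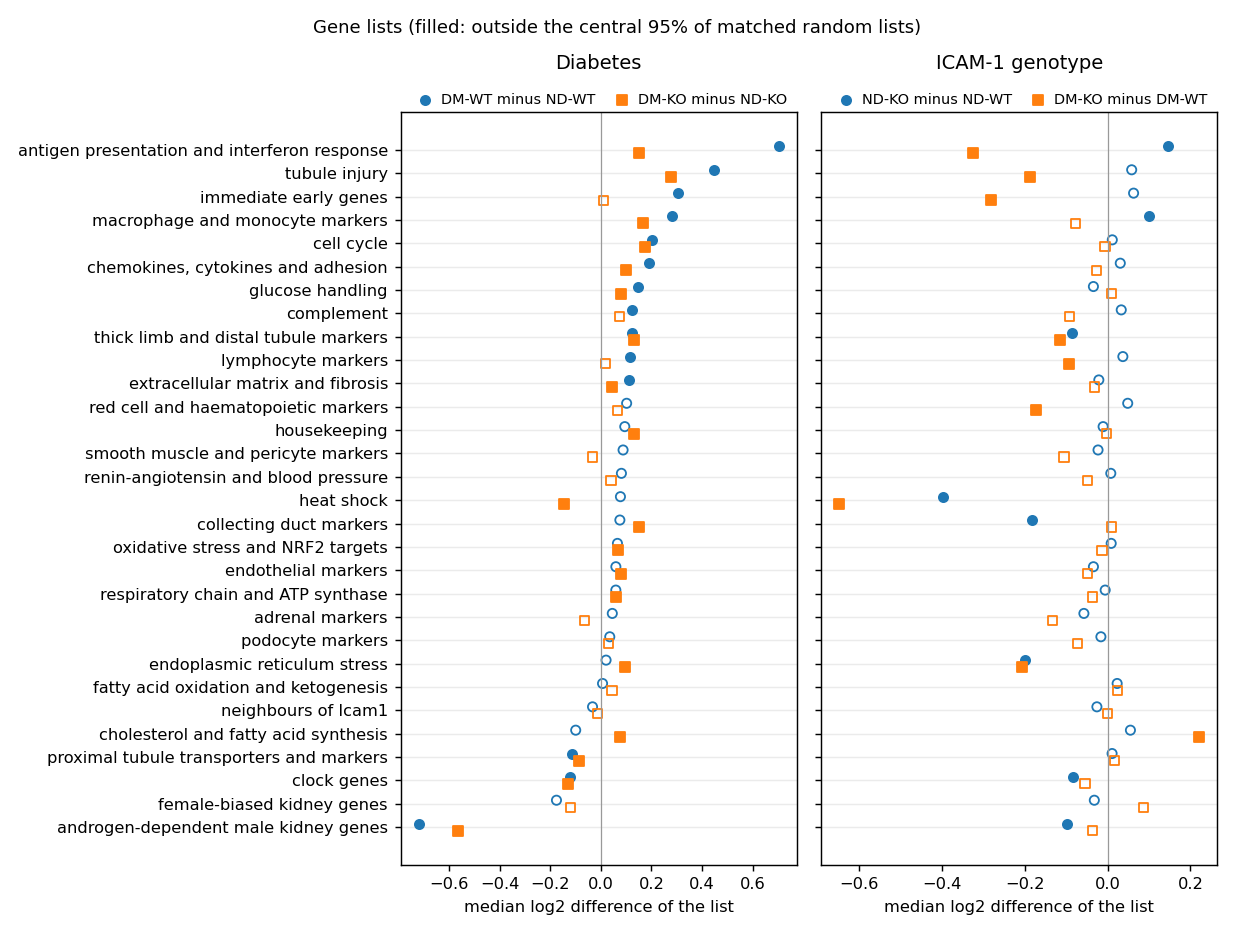
Median log2 difference of the measured members of each gene list (x axis) for diabetes in each genotype (left) and for genotype in each state (right), with filled symbols outside the central 95% of matched random lists. Interferon genes stood at 0.70 in WT and 0.15 in KO with diabetes, androgen-dependent genes at -0.72 and -0.57, and heat shock genes at -0.40 and -0.65 in KO against WT.

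The second comparison asked the same of mice without ICAM-1. Cyp4a14 was 4.01-fold higher on DM-KO than on ND-KO and Aldh1a1 3.31-fold higher. Aldh1a7 was 2.62-fold higher, the glutathione transferase Gsta2 2.11-fold, and Ephx1 and Ltc4s each 2.03-fold. The edge genes Pacsin2, Lamp2 and Hnf4a had log2 differences of 1.07, 0.95 and 0.93. Genes measured only on DM-KO were higher by at least 2.84-fold for Cdkn1a, 2.65-fold for Ugt1a2 and 1.62-fold for Phlda3. Cck stood 0.45 higher on the log2 scale.

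Lower on DM-KO were Akr1c18, a hydroxysteroid dehydrogenase, at -1.33, lipoprotein lipase Lpl at -1.22, and the oxysterol hydroxylase Cyp7b1 at -1.01. Hspa1b stood at -0.95, Acsm3 at -0.94, Nudt19 at -0.89, Ces1g at -0.88, Cyp4a12a at -0.87, Cpe at -0.85 and Bcat1 at -0.82. Hspa1b and Hspa1a are near-identical genes, so their values are uncertain. Genes measured on ND-KO and not on DM-KO were lower on DM-KO by at least 3.37-fold for the mitochondrial chaperonin Hspe1, 1.99-fold for Cfd and 1.57-fold for Matn2, with a smaller bound for Adipoq. Hspe1 had log2 intensities of 7.65 on ND-WT, 7.73 on DM-WT and 7.75 on ND-KO, and 5.71 on DM-KO alone. Hspd1, another member of the heat shock list, differed by only -0.15 in this comparison. A failed spot for Hspe1 on DM-KO was not excluded. Lpl, Cfd and Adipoq are adipocyte markers, and Cfd and Adipoq were above background on ND-KO alone of the 4 arrays. At least 2-fold differences numbered 9 higher and 3 lower of 6339 genes, and 8 and 3 of 6047 with edge spots left out.

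Androgen-dependent male kidney genes were again lower in 10 of 10 cases, 5 by at least 1.5-fold, with a median of -0.57 (percentile 0), including Cyp7b1 at -1.01, Acsm3 at -0.94 and Odc1 at -0.74. Tubule injury genes had a median of 0.28 (percentile 100), with Gdf15 at 0.87, S100a6 at 0.76, Spp1 at 0.65 and clusterin (Clu) at 0.49. Interferon and antigen presentation genes had a median of 0.15 (percentile 100), with 2 of 25 at least 1.5-fold higher and Irf7 at 0.59. Macrophage markers stood at 0.17 with Ctss at 0.42, cell cycle genes at 0.17 with Cdk1 at 0.40, collecting duct markers at 0.15 with the water channel Aqp2 at 0.91, and thick limb and distal tubule markers at 0.13 with Calb1 at 0.72. Smaller medians above the central 95% were 0.10 for chemokines, cytokines and adhesion, 0.10 for endoplasmic reticulum stress, 0.08 for glucose handling, 0.07 for cholesterol and fatty acid synthesis, 0.08 for endothelial markers, 0.07 for NRF2 targets and 0.04 for extracellular matrix. Respiratory chain genes at 0.06 and housekeeping genes at 0.13 were above it too, but lay below the median of all genes when the arrays were scaled by their medians or taken from the value table. Heat shock genes stood at -0.15 (percentile 0.10), with Hspa1a at -0.81, clock genes at -0.13 with Dbp at -0.68, and proximal tubule markers at -0.09, for which the mean was 0.00. Inside the central 95% were immediate early genes at 0.01, complement at 0.07, lymphocyte markers at 0.02 and fatty acid oxidation at 0.04. Under at least 1 alternative the calls for glucose handling, cholesterol synthesis, the respiratory chain, thick limb markers, endothelial markers and housekeeping genes ended, those for cholesterol synthesis and the respiratory chain also with edge spots left out (percentiles 84.7 and 97.2), and complement and fatty acid oxidation passed outside.

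Differences with diabetes were compared between the pairs, which share no array. Cyp4a14, Aldh1a1, Aldh1a7, Gsta2, Ephx1 and 1 unnamed probe were at least 2-fold higher in both genotypes, of 5914 genes measured on all arrays. None was at least 2-fold lower in both. Independent lists would share 0.0365 higher genes. At 1.5-fold, 22 genes were higher and 11 lower in both, against 0.492 and 0.281 for independent lists. Across genes, which are not independent replicates, the 2 sets of differences had a Pearson correlation of 0.48 and a Spearman correlation of 0.35.

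**Figure D3:**
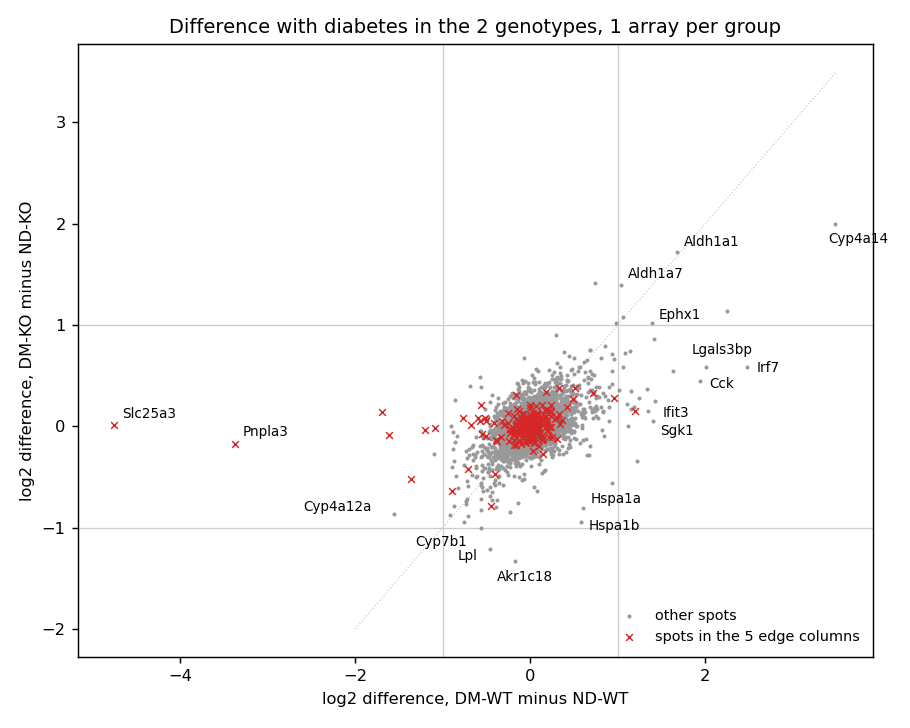
Log2 difference with diabetes in WT (x axis) and in KO (y axis) for each gene measured on all 4 arrays, with lines at 2-fold and crosses for genes in the 5 edge columns. Cyp4a14 lay at 3.49 and 2.00 and Aldh1a1 at 1.67 and 1.73, Irf7 at 2.48 and 0.59, and the edge gene Slc25a3 at -4.75 with almost no difference in KO.

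In the limma fit of diabetes with genotype as a covariate, Aldh1a1 rose by 1.70 on the log2 scale (SE 0.062, adjusted p = 0.0463 after Benjamini-Hochberg). It was the only gene of 6512 to pass, and 832 genes had an unadjusted p under 0.05, where 326 would by chance. The call ended, with 0 genes passing, under the series value table, an offset of 16, no background correction, an intensity trend and no covariate. With edge spots left out, limma called 52 genes that rose and 43 that fell among 6219, with 928 at an unadjusted p under 0.05. Of these 95 genes, 86 were measured on all 4 arrays, and the others rest in part on values not above background. Genes that rose in that fit included Gsta2 by 1.05 (SE 0.068, adjusted p = 0.0104), the leukotriene synthase Ltc4s by 1.00, Ephx1 by 1.20, betaine-homocysteine methyltransferase Bhmt by 0.82, Calb1 by 0.80 and Zmat3 by 0.74. Genes that fell included Ces1g at -0.90 (SE 0.068, adjusted p = 0.0140), Myo18b at -0.84, Acsm3 at -0.85, Odc1 at -0.75, Nudt19 at -0.81, C1qtnf3 at -0.73 and the kidney androgen-regulated gene Kap at -0.65. Cdkn1a and Phlda3 also passed there, but were not above background on either nondiabetic array, so only the bounds given for them hold. Cck was higher by 1.20 (SE 0.370, adjusted p = 0.335 by limma with Benjamini-Hochberg) and did not pass.

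Over all genes, 0 members of the gene lists passed in the fit with all spots, and Aldh1a1 belongs to none of them. Adjusted over the list alone, 10 of 10 androgen-dependent genes fell, and with edge spots left out 8 of 8 did, while 5 passed over all genes. Of 15 tubule injury genes 10 rose adjusted over the list alone, among them Clu, Cdkn1a, Gdf15, S100a6 and Anxa2. With edge spots left out 9 of 13 did, 4 of them over all genes. Of 17 macrophage markers, Cd14, Lyz2, C1qa, C1qb, C1qc and Ctss rose adjusted over the list alone and Fcgr2b fell. Among interferon genes 1 of 25 did so (Ifit2), and 12 of 23 with edge spots left out, including Irf7, Ifit1 and H2-Aa. Cell cycle genes had 6 of 18 (Ccnd1, Cdk1, Mcm5, Mcm6, Pcna and Birc5) and thick limb and distal tubule markers 5 higher of 14 (among them Slc12a3, Pvalb, Calb1 and Slc8a1) adjusted over the list alone, while Egf fell. For fatty acid oxidation, 6 of 28 rose adjusted over the list alone, among them Cyp4a14, Acot1 and Fabp1, and 3 fell, among them Bdh1 and Cyp4a12a.

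Among 35 oxidative stress and NRF2 targets, 4 rose adjusted over the list alone, including Gsta2 and Ephx1, and 2 fell, including Ces1g. With edge spots left out 5 of 33 passed over all genes, Gsta2, Gsta3, Gsta4, Ephx1 and Ces1g. Complement had 4 of 12 that rose adjusted over the list alone (C1qa, C1qb, C1qc and Serping1), and glucose handling 2 of 18. C1qa, C1qb and C1qc are also on the macrophage list, so of the complement calls only that of Serping1 is separate from the macrophage result. Clock genes had 1 that rose and 2 that fell of 14, Dbp being lower, and female-biased genes 1 and 2 of 5, Cyp4a14 being higher. Cryab among 13 heat shock genes, Agt among 12 renin-angiotensin genes and Tfrc among 6 red cell markers rose adjusted over the list alone. Chemokines had 0 with all spots and 6 of 24, including Cxcl10, with edge spots left out. Housekeeping genes had 3 of 13, 2 higher and 1 lower, adjusted over the list alone, so such calls also arose in a list not chosen for diabetes.

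The third comparison was of KO with WT mice without diabetes. Whether WT and KO mice also differed in genetic background was not tested. The median of the genes that neighbour Icam1 cannot decide this, because rises and falls among them would cancel, and Keap1 among them stood at -0.35. Plin2, which coats lipid droplets, was 2.68-fold lower on ND-KO than on ND-WT, with a log2 difference of -1.42. Manf, a secreted endoplasmic reticulum stress protein, stood at -1.06, Hspa1a at -0.95, the hypoxia-responsive Ndrg1 at -0.95, Hpd at -0.91, glucose-6-phosphatase G6pc at -0.91, Hsph1 at -0.86, the endoplasmic reticulum chaperone Hspa5 at -0.85 and Ugt2b37 at -0.80. Cyp4a14 was 2.18-fold higher, carboxypeptidase E (Cpe) 2.04-fold, Bcl6 1.85-fold, Tmem86a 1.70-fold, Stra6l 1.61-fold, the cold-inducible RNA-binding protein Cirbp 1.54-fold and Arsg 1.51-fold. The edge genes Sat1, Entpd4, Atp5g1 and Pacsin2 stood at 3.56, 0.92, 0.76 and -0.92, and Slc37a4 and Jun, also edge genes, were higher by at least 10.9-fold and 2.77-fold. Cfd, an adipocyte marker above background on ND-KO alone, was at least 1.93-fold higher and Col4a1 at least 1.64-fold lower. All 4 adipocyte markers measured on both arrays were also higher, among them Lpl at 0.46. At least 2-fold differences numbered 3 higher and 2 lower of 6258 genes, and 2 and 2 of 5974 with edge spots left out, but 8 and 15 in the series value table and 5 and 9 with an offset of 16.

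Heat shock genes were lower on ND-KO in 14 of 15 cases, with a median of -0.40 (percentile 0), including Hspa1a at -0.95, Hsph1 at -0.86 and Dnajb1 at -0.56. The near-identical Hspa1a and Hspa1b were counted separately here and in the heat shock medians of the other comparisons. Endoplasmic reticulum stress genes were lower in 18 of 20, with a median of -0.20 (percentile 0), including Manf, Hspa5 and Herpud1 at -0.71. Collecting duct markers stood at -0.18 (percentile 0), with Hsd11b2 at -0.40 and Aqp2 at -0.37. Thick limb markers stood at -0.09, androgen-dependent genes at -0.10 and clock genes at -0.08, with Per2 at -0.58 and Dbp at 0.48. Interferon genes stood at 0.15 (percentile 100), with Iigp1 at 0.38, and macrophage markers at 0.10 (percentile 99.7), with 14 of 14 higher. The medians of the other lists lay inside the central 95%, the lowest being adrenal markers at -0.06 and the highest immediate early genes at 0.06. The calls for androgen-dependent genes and clock genes ended under some alternatives (percentiles 4.70 and 3.31 in the series value table), while tubule injury and immediate early genes passed outside under others.

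The fourth comparison was of KO with WT mice under diabetes, with the same limit. Ugt1a2, a glucuronosyltransferase, stood at -2.56 on DM-KO relative to DM-WT, Hspa1a at -2.37, Hspa1b at -2.19, the deadenylase Noct at -2.10, Sgk1 at -2.09 and Irf7 at -1.79. Pdlim1 stood at -1.38, Rcan1 at -1.35, Plin2 at -1.34 and Lgals3bp at -1.32, and Cck at -1.04. Hspe1, Matn2, Per2 and Col4a1 were at least 3.32-fold, 2.08-fold, 1.74-fold and 1.74-fold lower, and the bound for Hspe1 again rests on its value on DM-KO, the only low one. Cirbp was 2.07-fold higher, bone morphogenetic protein Bmp6 2.05-fold and the sterol oxidase Msmo1 1.80-fold, and the other 7 of the 10 highest genes with a symbol were edge genes led by Slc25a3 at 4.77. At least 2-fold differences numbered 7 higher, 5 of them edge genes, and 19 lower of 6111, and 2 and 19 of 5882 with edge spots left out. With edge spots kept and no filter on dim probes the balance turned, to 40 higher and 23 lower. Bounds past 2-fold numbered 28 higher and 3 lower, and 1 and 3 with edge spots left out. Genes past such a bound are counted when there is no filter, so most of the 40 higher genes there rest on edge spots.

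Heat shock genes had a median of -0.65 (percentile 0), with Hspb1 at -1.16 and Dnajb1 at -0.96, and endoplasmic reticulum stress genes one of -0.21 (percentile 0), with Ddit3 at -1.22 and Herpud1 at -0.99. Interferon genes were lower in 24 of 24 cases, with a median of -0.32 (percentile 0), including Ifit1 at -1.02, Ifit3 at -0.98 and B2m at -0.96. Immediate early genes stood at -0.28 with Myc at -0.57, tubule injury genes at -0.19 with Cdkn1a at -0.62, red cell markers at -0.17, thick limb markers at -0.12 and lymphocyte markers at -0.09 with Ighm at -0.90. Cholesterol and fatty acid synthesis genes stood at 0.22 (percentile 100), higher in 12 of 14 cases, with Msmo1 at 0.85, Cyp51 at 0.61, Fdps at 0.44 and Sqle at 0.39. Macrophage markers at -0.08 and complement at -0.09 lay inside the central 95%, as did adrenal markers at -0.13 and smooth muscle markers at -0.11. All further lists also lay inside, between -0.07 for podocyte markers and 0.09 for female-biased genes. The calls for lymphocyte, thick limb and red cell markers ended under some alternatives, whereas macrophage, complement, adrenal and smooth muscle markers and NRF2 targets became low under others, adrenal markers also with edge spots left out (percentile 2.21).

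In the limma fit of genotype with diabetes as a covariate, Plin2 fell by 1.38 on the log2 scale (SE 0.064, adjusted p = 0.0421 after Benjamini-Hochberg). Its call ended under the same 5 alternatives as that of Aldh1a1, where 0 genes passed as lower. Slc37a4 and Sat1, both edge genes, were the other 2 of 6512 to pass, and neither was above background on DM-WT, while 594 genes had an unadjusted p under 0.05. With edge spots left out, limma called 12 of 6219 genes, 2 higher and 10 lower, with 687 at an unadjusted p under 0.05. Plin2 fell by 1.37 there (adjusted p = 0.00745 by limma with Benjamini-Hochberg), Ndrg1 by 0.93, Manf by 0.93, Herpud1 by 0.84, the mitochondrial transhydrogenase Nnt by 0.69, the haem synthesis enzyme Alas1 by 0.68 and Chordc1 by 0.66. Tmem86a rose by 0.77 and Arsg by 0.66, and 2 unnamed probes passed. The basement membrane collagen Col4a1 also passed, but was not above background on either KO array, so only its bounds hold. Because genetic background was not tested, none of these genotype differences, that of Nnt included, can be credited to the loss of ICAM-1 itself.

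Of 13 heat shock genes tested for genotype, 0 passed over all genes, while 9 fell adjusted over the list alone, among them Hspa1a, Hspb1, Hspa8, Hsp90aa1, Dnajb1 and Bag3. The 9 count the near-identical Hspa1a and Hspa1b separately. Of 20 endoplasmic reticulum stress genes 6 fell adjusted over the list alone (Hspa5, Ddit3, Xbp1, Dnajb9, Herpud1 and Manf), and with edge spots left out Herpud1 and Manf also passed over all genes. Of 14 clock genes, 5 fell adjusted over the list alone (among them Per2, Cry1, Bhlhe40 and Wee1) and Dbp rose. Plin2 alone passed among 28 fatty acid oxidation genes with all spots, and 3 of 27 did adjusted over the list alone with edge spots left out. Extracellular matrix had 3 of 34 that fell adjusted over the list alone, including Col4a1, and 1 that rose, and thick limb markers had 2 of 14 that fell, Pvalb and Calb1. Of 14 immediate early genes the edge gene Jun rose and Myc fell adjusted over the list alone, and of 9 podocyte markers Cdkn1c fell. With edge spots left out, 5 of 33 NRF2 targets rose and 2 fell adjusted over the list alone, 4 of 17 collecting duct markers fell, including Hsd11b2, and 2 of 13 cholesterol synthesis genes rose, Cyp51 and Msmo1. Over all genes, Plin2 passed with all spots and without edge spots, and Col4a1 only without edge spots.

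Whether the difference with diabetes depended on ICAM-1 was described by size only, because no residual spread is left once the interaction is in the model. Irf7 differed with diabetes by 1.89 less in KO than in WT on the log2 scale, an interaction of -1.89, followed by Noct at -1.57, Hspa1b at -1.53, Bcl6 at -1.50, Cck at -1.49, Cyp4a14 at -1.48, Lgals3bp at -1.42, Hspa1a at -1.41, Sgk1 at -1.35 and Rcan1 at -1.19. Bmp6 stood at 1.12, aldose reductase Akr1b3 at 1.09, the adenylyl cyclase Adcy6 at 1.06 and carbonic anhydrase Car2 at 0.95, and the other 6 of the 10 highest genes with a symbol were edge genes, Slc25a3, Pnpla3, Tbca, Acadsb, Orc3 and Usp14. Of 5914 genes, 9 had an interaction of at least 2-fold upward and 17 downward, and 3 and 15 of 5690 with edge spots left out. With no filter on dim probes, a setting that kept the edge spots, the counts were 36 and 22. Interferon genes had a median interaction of -0.48 (percentile 0), immediate early genes -0.30, heat shock genes -0.24, tubule injury genes -0.22, red cell markers -0.22, complement -0.18, macrophage markers -0.17, lymphocyte markers -0.12 and extracellular matrix -0.12. Cholesterol and fatty acid synthesis stood at 0.21, androgen-dependent genes at 0.15 and collecting duct markers at 0.11. Calls for androgen-dependent genes (percentile 93.6 with edge spots left out), lymphocyte markers (4.46 with edge spots left out), collecting duct markers (89.6 under median scaling), red cell markers and extracellular matrix ended under some alternatives. Fatty acid oxidation, chemokines and proximal tubule markers passed outside under others.

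Among the 36 genes at least 2-fold different with diabetes in WT and measured on all arrays, the median gene kept 0.244 of its WT difference in KO, and 0.301 over 28 genes with edge spots left out. A simulation with no genotype effect gave 0.922, and 0.908 with edge spots left out. Among the 11 genes at least 2-fold different in KO, the median gene had 0.965 of its KO difference in WT. The simulation drew noise from the nondiabetic pair for every array, whereas DM-WT was the dimmest array and correlated least with the others, so noise of that array alone was not simulated. At 2-fold the simulation chose 21 genes in WT and 20 in KO, against the 36 and 11 seen. It thus did not reproduce these arrays, and its 0.922 is a limited yardstick for them. The difference with diabetes in WT, the difference between genotypes under diabetes and the interaction all contain DM-WT, so they are not separate observations of its genes. Every other array is shared between comparisons in the same way. G6pc had log2 intensities of 11.07 on ND-WT, 10.21 on DM-WT, 10.16 on ND-KO and 10.01 on DM-KO. Its -0.86 with diabetes in WT and -0.91 on ND-KO relative to ND-WT therefore share the ND-WT value. Collecting duct markers, at -0.18 on ND-KO relative to ND-WT and 0.15 with diabetes in KO, share ND-KO.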

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

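Both tests of the edge of the DM-WT array and all 3 tests of the interferon genes were chosen only after the result was seen.

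The heat shock genes Hspa1a and Hspa1b moved in opposite directions with diabetes in the 2 genotypes. Hspa1a stood 0.61 higher on DM-WT than on ND-WT and at -0.81 on DM-KO relative to ND-KO on the log2 scale. Hspa1b stood at 0.59 and -0.95. The difference between the genotypes was not tested, because each group has 1 array, and the near-identical sequences of the 2 genes make them 1 observation rather than 2.

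On the DM-WT array, 92.1% of the bright probes that lay more than 2-fold below the other arrays were printed in columns 44 to 48 of the upper block, which hold 4.38% of all bright probes. A defect at that edge would place low probes there whatever their gene, as seen. A fall of these genes with diabetes would spread them over the array, but only 7.89% lay elsewhere, which argues against it as the cause for this set. A defect of the DM-WT array is therefore the likely source of the lower values of Slc25a3, Pnpla3, Tbca and the other edge genes, although single edge genes may also have changed. Sat1 and Slc37a4, which passed limma for genotype, are edge genes that were higher on both KO arrays. On ND-WT 3 of 176 bright edge probes (1.70%) were also low, against 0.262% of 3822 elsewhere, while 0 were low on ND-KO and DM-KO. Edge genes were 3 of the 10 highest for DM-KO against ND-KO and also for ND-KO against ND-WT, which do not use DM-WT. An effect of position on the other arrays is therefore not excluded.

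Genes of antigen presentation and interferon response were higher with diabetes by a median of 0.70 in WT and 0.15 in KO. Scaling, background or the array edge, as the whole cause, would have brought the interaction inside the central 95% under some setting. Its highest percentile over 10 settings was 0, with medians from -0.372 to -0.670, which argues against these steps, as varied here, as the whole cause. Some of the 10 settings changed none of these steps, and a shift common to all genes would move the random lists too. More immune cells in the DM-WT tissue could raise such genes, and the macrophage and lymphocyte medians of 0.281 and 0.117 in WT, against 0.704 for the interferon genes, neither reached that median nor stayed near 0, so this stays open. A dependence on ICAM-1 cannot be told apart from variation between mice or arrays with 1 array per group. An effect of the DM-WT RNA sample alone was not tested.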

How the results depend on the processing

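The setting without edge spots was chosen only after the result was seen, and all other alternatives were planned. The direction and call of 7 results, the interferon medians in WT, in DM-KO against DM-WT and in the interaction, the androgen-dependent medians in both genotypes and the heat shock medians in both genotype comparisons, were the same under every alternative run. Other results moved, and the cause was not tested except where stated. From 36, 12, 26 and 5 genes at least 2-fold different in DM-WT against ND-WT, DM-KO against ND-KO, DM-KO against DM-WT and ND-KO against ND-WT, the series value table gave 94 (62 higher, 32 lower), 31 (16, 15), 62 (21, 41) and 23 (8, 15). An offset of 16 gave 60 (45, 15), 22 (16, 6), 41 (12, 29) and 14 (5, 9). Both settings shrink log differences of dim probes less, by construction. No filter on dim probes gave 65 (31, 34), 63 (40, 23) and 9 (6, 3) for DM-WT against ND-WT, DM-KO against DM-WT and ND-KO against ND-WT. This setting kept the edge spots. By the bounds given above, they supply most of the 34 lower genes in the first comparison and of the 40 higher genes in the second. From 6 genes shared between genotypes, the value table gave 11, offset 16 gave 11 and median scaling 3. From 26 interactions of at least 2-fold, the value table gave 58 (18, 40), offset 16 gave 44 (15, 29) and no filter 58 (36, 22). For diabetes, limma called 1 gene, against 0 under the value table, offset 16, no background correction, an intensity trend and no covariate (649 to 831 at an unadjusted p under 0.05), 86 (31 higher, 55 lower) under median scaling, 19 (12, 7) under robust moderation and 95 (52, 43) without edge spots. For genotype it called 3, against 19 (8, 11) under median scaling, 7 (5, 2) under robust moderation, 1 (higher) under offset 16, 2 (both higher) under the value table, no background correction, an intensity trend and no covariate, so that the call of Plin2 ended under these 5, 1 among genes measured on all arrays and 12 (2, 10) without edge spots. Prior degrees of freedom were 3.19 with all spots and 5.01 without edge spots. Some medians turned sign. The gene list glucose handling relative to all genes, DM-WT against ND-WT, stood at -0.0233 under median scaling (percentile 84.1 among matched lists). The gene list respiratory chain and ATP synthase relative to all genes, DM-KO against ND-KO, stood at -0.0329 under the value table and -0.0275 under median scaling, and the gene list housekeeping relative to all genes, DM-KO against ND-KO, at -0.0266 and -0.0211, with percentiles of 88.8 and 87.0, and 73.9 and 73.4. Over both genotypes the respiratory chain turned to -0.0404 and NRF2 targets to -0.0312 under median scaling, yet among lists matched on level they lay at percentiles 97.0 and 89.8, above the middle but inside the central 95%. Median scaling moved the median of all genes by at most -0.0758. None of the 106 differences of named genes that were run turned sign (fewer in the value table, and 80 with edge spots left out), and differences of other genes in the text were not run. Their sizes did move, for 72 against 30 that stayed the same in the series value table. With an offset of 16, 57 moved and 49 stayed the same, and under median scaling 15 and 91. The fold values of many named genes therefore depend on the processing. The scanner software's own normalized intensity was not run, because the scanner tables used here hold no such values. No paired analysis was possible because each group has 1 array, and leaving out an array leaves no residual spread. Signal over background limits the dim probes, with a median subtracted intensity of 37.7 on DM-WT beside a background of 46.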

Other observations

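Of the tests of p53 target genes, the test on held-out genes was written before its result was seen, and the test over settings was chosen only after the result was seen.

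Some genes outside the comparisons' main lists are given as values. Adipocyte markers, cholecystokinin and gut hormone genes, neutrophil markers and skeletal muscle markers had 4, 2, 1 and 2 measured members in DM-WT against ND-WT, too few for a median. The adipocyte genes Car3, Fabp4, Lpl and Lipe stood at -0.85, 0.62, -0.46 and 0.12 in WT with diabetes and at -0.49, 0.09, -1.22 and 0.05 in KO. Adipoq and Cfd were above background on ND-KO alone, with log2 intensities of 6.58 and 6.99 there against 5.96 and 5.90 on ND-WT, 5.82 and 5.96 on DM-WT and 5.78 and 5.85 on DM-KO. Lpl was also highest on ND-KO, at 11.19. With dim values included, the adipocyte list lay at percentile 100 for ND-KO against ND-WT and 0.05 for DM-KO against ND-KO. The neutrophil gene Ngp stood at 0.07 and -0.19, and the muscle gene Tnni2 at 0.08 and 0.00. Parvalbumin (Pvalb), a distal tubule as well as a muscle gene, stood at 0.69 and 0.36. The clock output gene Dbp stood at -0.46 and -0.68 with diabetes and 0.48 higher on ND-KO than on ND-WT, and the circadian deadenylase Noct stood at -2.10 on DM-KO relative to DM-WT. The time of day at which kidneys were taken is not given in the sources used here.

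A set of p53 target genes was higher with diabetes in both genotypes, with Ccng1 at 1.09 in WT and 0.73 in KO, Gdf15 at 1.41 and 0.87, Zmat3 at 0.81 and 0.67, Plk2 at 0.94 and 0.55, Aen at 0.49 and 0.41 and Bax at 0.47 and 0.56, while Cdkn1a and Phlda3, not above background without diabetes, have only bounds of 4.28-fold and 2.84-fold and of 1.79-fold and 1.62-fold, and these 8 were chosen after their values were seen. As a test, 26 other p53 targets were written down, and after a first run Pmaip1 and Btg2 were taken out, because their values had been seen before the list was written. Of the remaining 24, 10 were measured in WT and 9 in KO, and their medians of 0.15 and 0.10 lay at percentiles 99.7 and 99.0 (99.9 and 99.5 over all 26), and at 97.1 in KO with no filter on dim probes, which is inside the central 95%. Over 8 settings the lowest median of the 8 noticed genes, dim values included, was 0.743, which decides nothing about scaling, background or the array edge, because the genes were chosen for large differences. A p53 response in the diabetic cortex rests on the held-out genes alone and is a hypothesis, and streptozotocin, which alkylates DNA, was given only to the diabetic mice and diabetes and the drug cannot be separated in this design.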
